A study of Mus musculus with 4 samples.

How the data were processed

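ChIP of RAR was done with 1 antibody from embryoid bodies treated with 5 µM all-trans retinoic acid for 2 h or 24 h, with 1 library at each time, per the labels. The deposited files list aligned reads, 1 line per read with its position and strand, and hold no peaks or counts. Reads were aligned with Bowtie to mm9, per the submitters' processing notes, and the version, the mismatches allowed and any filter on repeated matches are not given in the sources used here. Alignments on chromosome 1 reach base 197195426, and each library came from 1 lane by its read names. The deposited score column holds 1 value throughout, 0 at 2 h and 255 at 24 h, so it carries no measurement and was not used.

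Groups were taken from the sample titles. Reads on chromosomes 1 to 19, X and Y were used, and 1 read was kept per strand and start position, because 16.3% of the 2 h reads and 4.58% of the 24 h reads repeated a position. Keeping 1 read limits copies made by amplification, and also caps the height of the narrowest peaks.

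Fragment length was read from the distance between 5′ ends on opposite strands, with 1-kb bins above 8 times the mean left out. By this measure the strand column of the 2 h file read the opposite way from that of the 24 h file. The strands of the 2 h library were therefore exchanged, with fragments of 119 bp, while the 24 h library was used as deposited, with 145 bp. This was decided after the data were examined. Before it, peaks had been called in the full 2 h library with the column as deposited, which gave 2639, 1663 and 1061 peaks at assumed fragment lengths of 85, 145 and 200 bp. Numbers of peaks, overlaps and numbers of sites with the column as deposited are given beside the main ones. The named sites were only looked up among the sites called that way, and the regions, the overlap by strength, the random parts and the neighbour test were not run with it.

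Reads were shifted by a part of the fragment length to its centre and counted in bins of 50 bp. Windows of 200 bp were tested with a one-sided Poisson test against the higher of the genome mean and the surrounding 10 kb. Windows passed at Benjamini-Hochberg q under 0.001 and at least 5-fold, and windows up to 200 bp apart were joined. A peak also needed at least 20% of its reads on each strand, and minus-strand reads downstream of plus-strand reads by 0.25 to 2 fragment lengths. For peak calling the 2 h library was thinned at random to the 11965091 reads of the 24 h library. The genome mean was taken over 1-kb bins with at least 1 read in either library. Peak sets were compared by overlap of at least 1 bp, beside the overlap after a shift of 50 kb.

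Occupancy was compared at each site of the merged peak sets, with reads within 200 bp of the summit at the full depth of both libraries. The test was a two-sided exact conditional binomial test against the reads outside sites, 24221445 at 2 h and 11910291 at 24 h, with Benjamini-Hochberg adjustment over 6314 sites. A site passed at q under 0.05 and at least 2-fold, with 0.5 reads added for the log2 ratio only. Enrichment is the reads within 200 bp of the summit over the genome mean for 400 bp, which was 3.83 reads at 2 h and 1.87 at 24 h. At this depth a single read at 24 h is worth more than at 2 h, and low values there are coarse. Intervals are 95% exact binomial intervals, and a count of 0 was set to a floor of 3 reads for a bound. Flanks are 1 to 5 kb on either side of the summit, and for scaling 5 reads were added to those at 2 h, and a number in proportion to depth at 24 h. Calculations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1, and figures used matplotlib 3.10.9.

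The named sites follow a rule set before the data were examined: the 10 sites with the smallest p of those higher at each time, and the 10 with the most depth-scaled reads of those called in both. Together these are 28 sites. The peak caller and the occupancy test were tested on simulated data with an even background and counting error only, without repeats or pile-ups. The few false peaks and calls there therefore do not give the rate in the real libraries. In a simulated 2 h library, the caller recovered 2.5% of 200 sites planted at 5 times the background, 32.5% at 10 times and 96.5% at 20 times. In a simulated 24 h library it recovered 4%, 43% and 96.5%, and neither library gave a peak away from the planted sites. Of 132 recovered sites planted at 2 h only, 124 were called higher at 2 h, and of 150 planted at 24 h only, 149 were called higher at 24 h. Of 167 planted in both, 4 were called higher at 24 h and 1 higher at 2 h.

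Alternatives covered depth, repeated positions, thresholds, background, strand filters, overlap, scaling and counting width. Those chosen after the data were examined were the strand column, random parts of the reads, scaling by chromosome or flanks, limits on flanks, 2 h peaks from the full library, and leaving out pile-ups. A set of 4 planned tests was not run, because no mm9 sequence or annotation was used here: receptor half-site spacing, other motifs, position relative to genes, and occupancy near fixed gene lists. For the same reason sites are named by position and not by gene. The gene table at hand is for another build, and no position was converted.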

Results

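The retinoic acid receptor (RAR) is a nuclear receptor that binds DNA and changes transcription when its ligand, retinoic acid, is present. RAR-bound DNA was isolated by chromatin immunoprecipitation (ChIP) from mouse embryonic stem cells that had been grown for 4 days as embryoid bodies, the floating aggregates in which such cells begin to differentiate. The embryoid bodies then received 5 µM all-trans retinoic acid. A single ChIP library was sequenced after 2 h of treatment and another after 24 h. The 2 h library held 29279910 aligned reads and 24487990 distinct read positions on chromosomes 1 to 19, X and Y. The 24 h library held 12543290 aligned reads and 11965091 distinct positions. There were no replicates, so every test below compares these libraries and not the times of treatment, and intervals cover counting error only. Reads were 54 bp long at 2 h and 36 bp at 24 h. Read length, sequencing lane, any difference in the handling of the files, and time therefore cannot be told apart. No input or control-antibody library was used here, and background was taken from the surrounding genome of the same library. The labels also list 2 RNA-seq samples, which were not analysed here. The series title concerns movement of the receptor between binding elements of different spacing. Element spacing was not analysed here, and the comparisons below cover where the receptor sat at each time. All positions are on the mm9 build.

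The first comparison asked how many sites the receptor occupied soon after retinoic acid and a day later. At equal depth, 5467 RAR peaks were called at 2 h and 1216 at 24 h, a ratio of 4.50. The peaks held 1.07% of the reads at 2 h and 0.232% at 24 h. The median height was 10.7 times the background at 2 h and 9.38 times at 24 h, and the median peak was 300 bp wide in both libraries. These heights depend in part on the thresholds that call a peak, since few of the sites simulated at 5 times the background were recovered (2.5% at 2 h and 4% at 24 h). Peaks were most numerous on chromosome 11 at 2 h, with 402 there and 99 on the same chromosome at 24 h. At 24 h chromosome 8 held more peaks than any other chromosome, 112, against 291 there at 2 h.

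The order of these numbers, once strand filters are applied, rests on how the strand column of the 2 h file is read, a choice made after the data were examined. As deposited, reads of opposite strands in that library pointed away from each other, with their 5′ ends most often -13 bp apart. With the strands exchanged they pointed toward each other at 119 bp, as a ChIP fragment gives. In the 24 h library they did so at 145 bp as deposited. With the column exchanged, 91.9% of 5946 enriched regions at 2 h passed the strand filters. With the column as deposited, 24.98% of 4652 regions passed, which left 1162 peaks at 2 h, fewer than the 1216 at 24 h, where 71.1% of 1710 regions passed. Before the filters there were thus more regions at 2 h with the column read either way. The filters ask for minus-strand reads downstream of plus-strand reads, which reads that point away from each other fail.

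**Figure D1:**
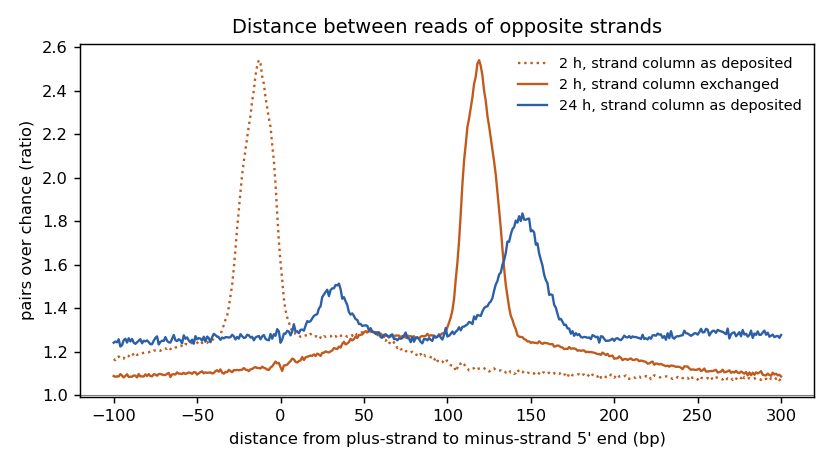
Number of read pairs on opposite strands relative to chance (y axis, ratio) against the distance from the plus-strand to the minus-strand 5′ end (x axis, bp), for the 2 h library read both ways and the 24 h library as deposited. The 2 h curve peaks at -13 bp as deposited and at 119 bp after the exchange, and the 24 h curve peaks at 145 bp.

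The peak sets of both times shared few sites. Of the 2 h peaks, 368 of 5467 overlapped a 24 h peak by at least 1 bp, or 6.73% (95% exact binomial interval 6.08 to 7.43%). Of the 24 h peaks, 369 of 1216 overlapped a 2 h peak, or 30.3% (27.8 to 33.02%). After a shift of 50 kb, 2 peaks of each set overlapped. Where peaks overlapped, 84.2% of the 2 h summits lay within 50 bp of a 24 h summit. Stronger peaks were shared more often: of the 1366 strongest 2 h peaks 11.8% (10.1 to 13.6%) overlapped a 24 h peak, and of the 1367 weakest 4.54% (3.49 to 5.78%). Of the 304 strongest 24 h peaks 38.2% (32.7 to 43.9%) overlapped a 2 h peak, and of the 304 weakest 23.7% (19.02 to 28.9%).

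Random parts of one library also shared only some of their peaks. At 5979537 reads per part, 60.1% of the peaks of one 2 h part were called in the other 2 h part, and 38.3% of the peaks of one 24 h part in the other 24 h part. Between a 2 h part and a 24 h part, 4.34% of the 2 h peaks and 27.4% of the 24 h peaks were shared. With the strand column of the 2 h file as deposited, which left fewer 2 h peaks, 6.91% of the 24 h peaks overlapped a 2 h peak and 7.14% of the 2 h peaks overlapped a 24 h peak.

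The next comparison counted the reads of both libraries at each of the 6314 sites called in at least 1 of them. RAR occupancy was higher at 2 h at 3995 sites and higher at 24 h at 713, while 1606 sites passed in neither direction. The 3995 sites stood at a median of 10.7 times the genome mean at 2 h and 1.602 times at 24 h. The 713 sites stood at 2.35 times at 2 h and 10.7 times at 24 h. The test was a two-sided exact binomial test per site with Benjamini-Hochberg q under 0.05 and at least a 2-fold difference.

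Some sites were above background at the time of lower occupancy too. At 355 of the 713 sites higher at 24 h (49.8%) the 2 h library exceeded its own background, at an unadjusted p under 0.05. This held in the 24 h library for 860 of the 3995 sites higher at 2 h (21.5%), where the median was 3 reads and 20.2 would have been seen at the level of the 2 h library. These shares come from libraries of different depth and are not set against each other. Of the 368 sites called in both libraries, 64 were higher at 2 h, 39 were higher at 24 h and 265 passed in neither direction, with a median log2 ratio of 24 h over 2 h of -0.09. Sites were chosen on the reads that were then compared, which favours a difference. With sites called on one random part of the reads and counted in the other part, 1512 sites of 2639 were higher at 2 h and 168 higher at 24 h. With the strand column as deposited, 839 sites were higher at 2 h and 721 higher at 24 h.

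**Figure D2:**
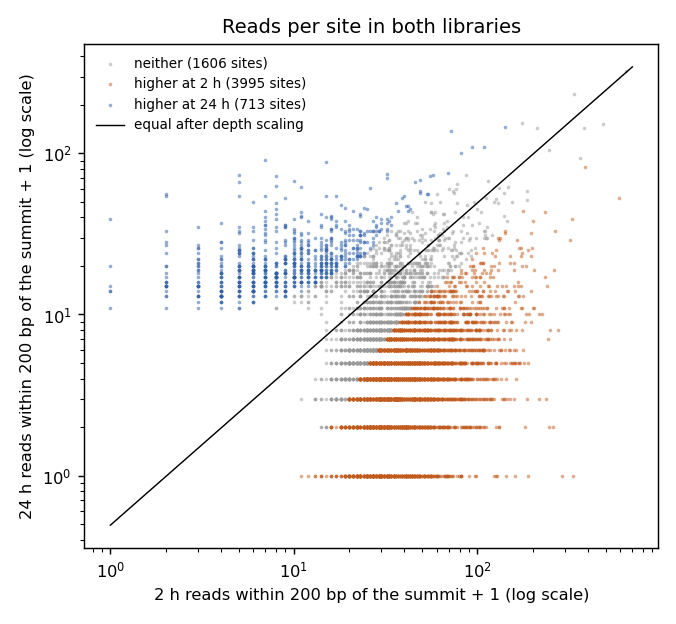
Reads within 200 bp of the summit of each site, plus 1, at 24 h (y axis, log scale) against 2 h (x axis, log scale), at the full depth of each library. Each point is a site, coloured by class, and the line marks equal occupancy after scaling by reads outside sites; 3995 sites were called higher at 2 h, 713 higher at 24 h and 1606 in neither direction.

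**Figure D3:**
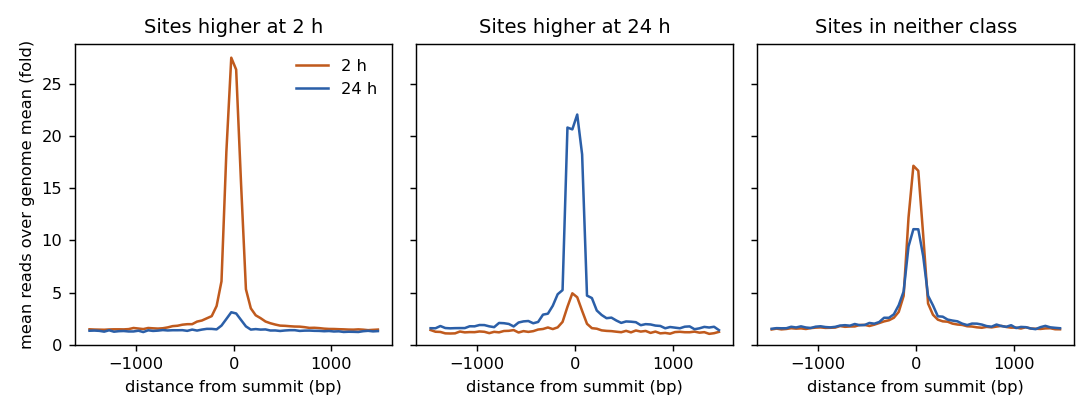
Mean reads per 50 bp relative to the genome mean (y axis, fold) against distance from the site summit (x axis, bp) in both libraries, for the 3995 sites higher at 2 h, the 713 sites higher at 24 h and the 1606 sites in neither class. Each class was chosen on these reads.

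Among the 10 sites with the smallest p of those higher at 24 h, the 2 h library held 1 to 71 reads and the 24 h library 53 to 137, and the fold ranged from 3.92 to 112. On chromosome 17, the site at bases 29551101 to 29551550 had 1 read at 2 h and 55 at 24 h, a 112-fold difference (95% interval 19.3 to 4497, exact binomial p = 2.35e-25). On chromosome 4, that at 124546351 to 124546850 had 1 and 53 reads, a 108-fold difference (18.5 to 4337). On chromosome 12 at 70712101 to 70712900, 4 reads stood against 72, and on chromosome 7 at 134920351 to 134921000, 4 against 65. These differences were 36.6-fold (13.7 to 138) and 33.05-fold (12.3 to 125). Occupancy at 27489001 to 27489450 of chromosome 14 was 20.6-fold higher (9.51 to 53.2). On chromosome 9 at 99468901 to 99469400 it was 18.01-fold higher (8.24 to 46.7), and on chromosome 6 at 113256751 to 113257250 it was 14.9-fold higher (7.40 to 34.05).

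The other 3 sites of this group lay on chromosome 8, which held more of the 24 h reads as a whole. The site at 27945401 to 27946050 had 6 reads at 2 h and 90 at 24 h and was 30.5-fold higher (13.5 to 85.3). The site at 73353301 to 73353800 was 12.6-fold higher (7.14 to 24.1). The site at 73215601 to 73216100 had 71 and 137 reads and was 3.92-fold higher (2.93 to 5.30). Scaled by reads outside sites on chromosome 8 alone, their log2 ratios were 4.33, 3.12 and 1.47, and all 3 calls stood. Scaled by their own flanks, the sites at 27945401 and 73353301 had log2 ratios of 3.84 and 2.36, from 4.82 and 3.62, and kept the call. The site at 73215601 to 73216100 then had a log2 ratio of 0.91 and lost it. In 1-Mb bins outside sites, chromosome 8 held 1.38 times the 24 h reads relative to 2 h that the autosomes held in the median. The other 18 autosomes ranged from 0.918 to 1.11 and chromosome X stood at 0.713. Of the 713 sites higher at 24 h, 87 lay on chromosome 8, and 71 of 710 with scaling by chromosome.

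**Figure D4:**
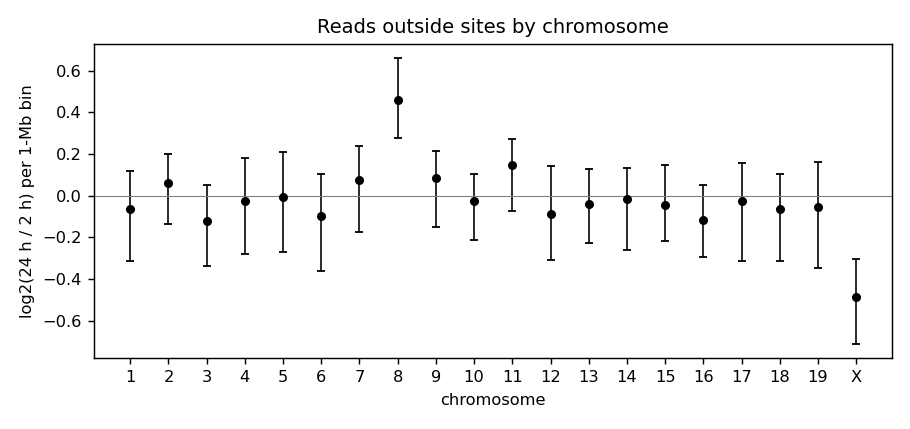
Median log2 ratio of 24 h over 2 h reads in 1-Mb bins outside sites (y axis), relative to the median autosomal bin, for chromosomes 1 to 19 and X (x axis). Points are medians and bars span the quartiles of the bins; chromosome 8 stands at 0.46 and chromosome X at -0.49.

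Among the 10 sites with the smallest p of those higher at 2 h, the 2 h library held 217 to 593 reads and the 24 h library 0 to 52. A pair of them lay on chromosome 17. At bases 6478301 to 6478850 the libraries had 257 reads at 2 h and 1 at 24 h, a 126-fold difference (22.5 to 5011, exact binomial p = 3.95e-43). At 6267651 to 6268150 they had 244 and 1 reads, a 119.98-fold difference (21.3 to 4758), but the flanks held 0.240 of the mean 24 h reads. Scaled by their flanks, these sites had log2 ratios of -4.46 and -3.15 in place of -6.40 and -6.32, and the flanks of the first held 3.64 times the mean 2 h reads. Occupancy on chromosome 2 at 57481801 to 57482250 was 58.02-fold higher at 2 h (15.9 to 482). On chromosome 5 at 101765551 to 101766200 it was 53.4-fold higher (14.6 to 443). The chromosome 2 site carried 2.44 reads per position at 2 h, and its flanks held 0.454 of the mean 24 h reads. The site on chromosome 6 at 140554301 to 140554750 had 276 reads against 7 and was 19.4-fold higher (9.28 to 48.7). That on chromosome 7 at 4772501 to 4773050 had 241 against 6 and was 19.8-fold higher (8.94 to 54.4). Another site on chromosome 6, at 47982601 to 47983150, was 17.4-fold higher (8.30 to 43.6). Flank scaling took the sites on chromosomes 2 and 5 to log2 ratios of -4.62 and -4.74, from -5.54 and -5.42. It took the site at 140554301 to 140554750 of chromosome 6 to -3.08, from -4.18, and that on chromosome 7 to -3.56, from -4.19, and all kept their call.

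The remaining sites of this group also had limits. Near the end of chromosome X, the sites at 166527101 to 166527650 and at 166649901 to 166650296 had 331 and 290 reads at 2 h and 0 at 24 h. Against a floor of 3 reads in the 24 h library, these were at least 54.3-fold and 47.5-fold higher. Their 95% exact intervals reached down to 43.9-fold and 38.4-fold, and the flanks of both sites held 0 reads at 24 h. Scaled by reads outside sites on chromosome X alone, their log2 ratios were -7.71 and -7.52, from -8.35 and -8.16, so the bounds above would be lower too. With flank scaling the log2 ratios were -5.62 and -5.72, values that rest on reads added to the empty flanks. These sites carried 4.69 and 3.6 reads per position at 2 h, and the first lay in a 1-kb bin that held 1562 reads of that library. The site on chromosome 15 at 74916101 to 74917550 had 593 reads at 2 h and 52 at 24 h, a 5.61-fold difference (4.22 to 7.60). It carried 4.17 reads per position at 2 h, and lost its call with flank scaling, at a log2 ratio of -0.63.

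The 10 sites with the most reads among those called in both libraries were called higher at 2 h in 6 cases, higher at 24 h in 2 and in neither direction in 2. They included the sites described above on chromosome 15 and on chromosome 8 at 73215601 to 73216100. On chromosome 2, the site at 30634701 to 30635350 had 174 reads at 2 h and 154 at 24 h, and its ratio of 1.80 (1.44 to 2.25) lay under the 2-fold minimum. Counted within 100 bp of the summit it passed, at a log2 ratio of 1.18. On chromosome 16, the one at 76225301 to 76225900 had 186 and 57 reads, and its ratio of 1.605 in favour of 2 h (1.19 to 2.20) did not pass either. That on chromosome 4 at 154563801 to 154564350 had 108 reads in each library, which made it 2.03-fold higher at 24 h (1.54 to 2.68), and it lost the call with flank scaling, at a log2 ratio of 0.41.

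Higher at 2 h among them were the sites on chromosome 1 at 184430901 to 184431500 (5.64-fold, 3.83 to 8.62) and on chromosome 3 at 152396051 to 152396950 (4.23-fold, 3.02 to 6.09). Flank scaling took the first of these to a log2 ratio of -3.12, from -2.47. Also higher at 2 h were those on chromosome 9 at 103274901 to 103275450 (4.04-fold, 2.79 to 6.03) and on chromosome 12 at 3238451 to 3239000 (2.73-fold, 1.96 to 3.89). The site on chromosome 12 at 3109751 to 3110300 was 2.33-fold higher at 2 h (1.83 to 2.99), but carried 443 reads per position in that library. With flank scaling its log2 ratio turned to 0.70 in favour of 24 h, under the 2-fold minimum, and within 100 bp of the summit, at -0.81, it did not pass.

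The regions that held the most sites that passed were named after their values were seen. Of all 4708 sites that passed, 3995 were higher at 2 h, so a stretch higher at 2 h throughout does not by itself set a region apart. On chromosome 13, between 44735851 and 44831200, all 8 sites that passed were higher at 2 h. Among those with reads in both libraries, the largest difference was at 44773351 to 44773700, with 79 reads at 2 h and 4 at 24 h. It was 9.71-fold (3.65 to 36.5). The smallest was at 44803001 to 44803350, with 37 reads and 7, and was 2.60-fold (1.14 to 6.91). On chromosome 6, between 39355201 and 39419750, another 8 sites were all higher at 2 h, each by at least 2.77-fold. There the site at 39370851 to 39371300 had 138 reads against 7, a 9.69-fold difference (4.58 to 24.6).

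The longest stretch in which each site that passed was higher at 24 h lay on chromosome 11, between 96156801 and 96234400, with 5 sites and differences of 3.16-fold to 8.13-fold. The site at 96202401 to 96202750 had 10 reads at 2 h and 40 at 24 h, an 8.13-fold difference (4.00 to 18.2). The site at 96233901 to 96234400 had 31 and 69 reads, a 4.53-fold difference (2.92 to 7.16). The flanks of these 5 sites held at least 1.63 times the mean 24 h reads.

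**Figure D5:**
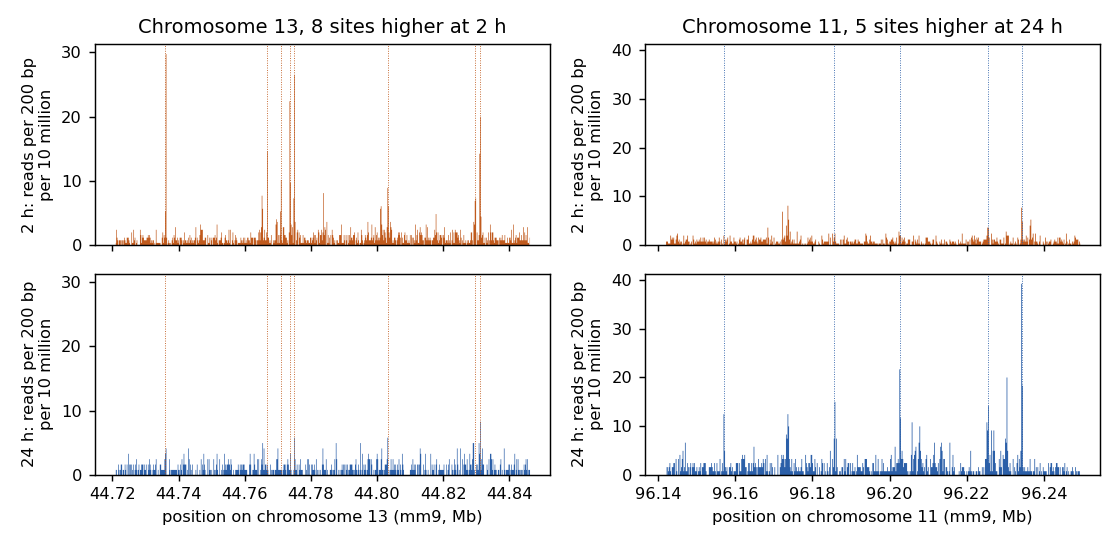
Reads per 200 bp, scaled to 10000000 distinct reads (y axes) at 2 h (top) and 24 h (bottom) along 2 regions of mm9 (x axes, Mb), the stretch of chromosome 13 with 8 sites higher at 2 h and the stretch of chromosome 11 with 5 sites higher at 24 h. Dotted lines mark the summits of the sites that passed; the 8 sites stand out in the upper panel on the left and the 5 sites in the lower panel on the right.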

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

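The tests in this part of the strand column, of chromosome 8, of depth and of sites called on one part of the reads were chosen after the results were seen; the tests of read placement and of scatter around a common share were set before.

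Mitochondrial reads, which were outside the comparisons, and pile-ups, which were not, were looked at because they rose above a count of 0. Mitochondrial DNA held 28770 reads at 2 h and 3713 reads at 24 h, or 0.098% and 0.030% of aligned reads. Bins of 1 kb with 1000 or more reads held 6.77% of the reads at 2 h and 0.291% at 24 h. Most of these reads at 2 h lay on chromosome 2, with 909827 in 7 bins, and on chromosome 9, with 820689 in 41 bins. These bins were kept in the main peak calling and occupancy test, with 1 read per strand and start position. Leaving them out gave 5458 peaks at 2 h and 1209 at 24 h. The named sites on chromosome 12 at 3109751, chromosome 15 at 74916101 and chromosome X at 166527101 overlapped such bins of the 2 h library.

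In the 2 h file, reads of opposite strands pointed away from each other. A shift of reads toward fragment centres before deposit would have moved some past the assembled start of chromosomes 1 to 19 and X, and 0 reads of the 2 h library started before it there. An exchanged strand column is a candidate explanation that stays open. With the strands exchanged, opposite-strand pairs at 119 bp were 2.30 times as frequent as at 250 to 300 bp, but exchanging the labels of 54-bp reads mirrors the excess at -13 bp to that distance, so this value restates the pattern and decides nothing.

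Chromosome 8 held more of the 24 h reads than of the 2 h reads. More receptor binding there is argued against by reads outside sites, whose share on chromosome 8 was higher at 24 h by 0.49 on the log2 scale. A few pile-ups are argued against by the median 1-Mb bin, higher by 0.46, and 94.4% of its 126 bins lay above the autosomal median. An extra copy of chromosome 8 in the 24 h culture may account for the pattern: the ratio was 1.38, and such a gain is known from cultured mouse embryonic stem cells. GC content was not tested without mm9 sequence, so a sequencing difference between the libraries stays open, as for chromosome X at 0.713.

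More peaks were called at 2 h than at 24 h. With the strands exchanged, depth is argued against by a ratio of 4.50 at equal depth. Of the sites higher at 2 h, 88.0% had flanks with 0.5 to 2 times the mean 24 h reads. This argues against a failure to place 36-bp reads around these sites. Flanks lie 1 to 5 kb from the summit and cannot show whether reads could be placed at the summit itself, so that stays open. Among sites called on one part of the reads, 168 were higher at 24 h in the other part. There the q threshold, which covers counting error only, allows 84 false calls among 1680. More sites were thus higher at 24 h than counting error allows. Both parts come from the same libraries, so this cannot decide whether enrichment at 24 h was uniformly weaker. The scatter of 24 h reads at 2 h peaks around 1 common share of the 2 h excess, 8.23 times Poisson, decides nothing, since without replicates it can be set against counting error alone. A loss of enrichment that differs between sites, in the cells or in the ChIP, cannot be told apart from time, read length or lane. Nor can it be told apart from any difference in how the files were aligned or filtered, which is not given. Bins of 1 kb with 1000 or more reads held 6.77% of the 2 h reads and 0.291% of the 24 h reads. With the strand column as deposited, the order of the peak numbers was the opposite after the strand filters (1162 against 1216). Before them it was not (4652 against 1710 regions).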

How the results depend on the processing

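The strand column, parts of the reads, scaling by chromosome or flanks, limits on flanks, peaks of the full library and pile-ups were alternatives chosen after seeing the data. At full depth 10867 peaks were called at 2 h, and 42.6% of the 24 h and 4.76% of the 2 h peaks overlapped. With all reads kept, 23.7% of the 24 h peaks overlapped and 1152 sites were higher at 24 h. At q under 1e-06 there were 3199 and 547 peaks at 2 h and 24 h, 5.60% of the 2 h peaks overlapped, and 2642 and 314 sites were higher at 2 h and 24 h, since fewer windows pass. At least 10-fold enrichment left 3337 and 470 peaks, and the genome mean alone as background gave 9186 and 3422. With the 2 h strand column as deposited there were 1162 peaks at 2 h, from 4652 regions before the strand filters, 6.91% of the 24 h and 7.14% of the 2 h peaks overlapped, and 839 sites were higher at 2 h. Of these, 580 overlapped a site called so with the column exchanged. With 2 h peaks from the full library, 6110 sites were higher at 2 h. Calling on one part of the reads gave 2378 and 368 peaks, and counting in the other part left 1512 sites higher at 2 h and 168 at 24 h; fewer reads and the separate choice of sites both act here. For the rest, the cause was not tested.

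With total reads, the shared-site median, a 3-fold minimum, 100-bp counts, scaling by chromosome or flanks, or limits on flanks, sites higher at 2 h numbered 3283 to 4198 and sites higher at 24 h 534 to 748. Of the 28 named sites, all kept their call or lack of one under total reads, the shared-site median and scaling by chromosome. Within 100 bp of the summit 26 did, 1 lost its call and 1 gained one. This moved 8 ratios by more than 1.5-fold, in log2 values on chromosome 17 from 6.23 to 7.56 (site at 29551101), from -6.40 to -7.57 (6478301) and from -6.32 to -7.43 (6267651), on chromosome 6 from -4.02 to -5.36 (47982601) and from 3.83 to 4.85 (113256751), on chromosome 9 from 4.08 to 4.79 (99468901) and from -2.00 to -2.59 (103274901), and on chromosome 5 from -5.42 to -4.37. With the strand column as deposited, 24 overlapped a site with the same call, among them 11 of the 15 higher at 2 h. With flank scaling 24 kept their call or lack of one, 3 lost the call with the same sign, and 1 lost it with its sign turned, the site on chromosome 12 at 3109751 to 3110300, at a log2 ratio of 0.70. Of the 3995 sites higher at 2 h, 3572 kept that call with flank scaling, as did 556 of the 713 higher at 24 h. By overlap of sites, 3108 and 657 kept it with all reads kept, 3797 and 704 with 2 h peaks from the full library, 580 and 698 with the strand column as deposited, and 1429 and 143 with sites called on one part of the reads. Omitting the strand filters, another thinning seed and leaving out pile-ups moved the numbers of peaks by less than 1.5 times. Overlap by summits within 100 bp left both overlaps within their intervals.

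Weaker sites were mostly missed: in simulated libraries 2.5% (2 h) and 4% (24 h) of sites at 5 times the background were recovered. These sites stood at the 5-fold minimum of the caller, and no other depth was simulated. The loss therefore cannot be assigned to depth or to the thresholds. No paired analysis was possible because each time had 1 library. The planned tests of half-site spacing, other motifs, gene positions and gene lists, with their alternatives, were not run.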

Other observations

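The test of neighbouring sites, also with flank scaling, was set before its results were seen, though flank scaling itself was added after the data were examined. Leaving out chromosome 8 was chosen after its excess of 24 h reads was seen, and the regions named were chosen after their values.

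Of 4708 sites that passed, 1635 (34.7%) lay within 50 kb of another one, in 672 groups, of which 22 held 5 sites or more. This was not compared with chance placement. Since 3995 of the 4708 sites were higher at 2 h, groups in which all sites were higher at 2 h do not by themselves stand out. On chromosome 17, between 27134501 and 27282650, 7 sites were all higher at 2 h, as were 7 sites on chromosome 5 between 134815801 and 134921700. Another 7 sites higher at 2 h lay on chromosome 13 between 65481901 and 65664700, where the flanks of a site held as little as 0.027 of the mean 24 h reads. On chromosome Y, 4 sites between 1751751 and 1769350 were all higher at 24 h, with flanks down to 0.374 of the mean.

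The hypothesis that sites close together change in the same direction was tested on 927 pairs of neighbours 1 to 50 kb apart. The direction was the same in 777 pairs, or 83.8%, against a mean of 74.8% when directions were permuted within chromosomes (one-sided permutation test, p = 1e-05, the smallest that 100000 permutations can give). Pairs in which both sites were higher at 24 h numbered 40, against 27.5 permuted (permutation p = 0.0073); with flank scaling they numbered 27 against 18.7 (permutation p = 0.029), and without chromosome 8 they numbered 32 against 21.8 (permutation p = 0.012). With each site scaled by its flanks the shares were 84.5% and 77.3% (permutation p = 1e-05), and without chromosome 8 they were 84.5% and 76.0% (permutation p = 1e-05). Neighbouring sites may thus share their direction over up to 50 kb in these libraries. With flank scaling the share stayed above the permuted one, but where flanks are nearly empty this scaling rests on the added reads. On chromosome 13, flanks at 24 h fell to 0.027 of the mean among the 7 sites from 65481901, all higher at 2 h. They fell to 0 among 6 sites from 65847751, also all higher at 2 h. The test set no limit on flanks, so it cannot decide whether differences in the surrounding reads are the whole cause. Whether shared chromatin underlies the pattern was not tested.

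Across the 5467 sites called at 2 h, reads at 2 h and 24 h were weakly related (Spearman's rho 0.24, across sites, which are not independent replicates). Together these sites kept 20.6% of the depth-scaled 2 h excess at 24 h. The sites were chosen on the 2 h reads used here, which favours a low value of both. The same was not computed for sites called at 24 h. Chromosome X held 0.568 of the autosomal read density at 2 h and 0.406 at 24 h.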
